A study of Danio rerio with 6 samples.

How the data were processed

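Small RNA from pooled hearts of adult Ekkwill zebrafish was measured on a microRNA (miRNA) array. There were 3 samples from uninjured hearts and 3 from regenerating hearts taken 6 hours after part of the heart had been removed; the series design calls the replicates biological. Per the labels' protocols, a service company size-selected the RNA below 300 nucleotides, gave it a poly(A) tail and an oligonucleotide tag, and stained it with Cy3 or Cy5. In each group 2 samples carried Cy3 and 1 carried Cy5.

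The deposited file of each sample gives, per the file headers, the mean intensity of every spot and its spread within the spot, on a linear scale. The values show no background subtraction. The array held 3968 spots: 218 zebrafish miRNA probes with 12 spots each, 1060 empty spots, 268 spots for added calibration sequences with their mismatched partners, and 24 spots for 5S ribosomal RNA. The scanner and image software are not given in the sources used here. A value table of the whole series holds the authors' processed intensities of the same probes; its values are linear, and the method of background subtraction and scaling is not given in the sources used here. Each column of that table correlated with the log2 values computed here from the same sample at r of 0.991 to 0.993, so direction and log base were settled; its column medians ran from 68.9 to 91.9. It served as an alternative.

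The files have no background column, so the local background of a spot was taken as the median of the 16 nearest empty spots. Intensities were corrected with limma 3.58.1 in R 4.3.3 (normexp with offset 50, fitted on all spots), converted to log2 and averaged over the 12 spots of a probe. Quantile normalization between arrays was run over the 218 miRNA probes, with control and empty spots left out. A probe counted as detected in a sample when its background-subtracted mean exceeded 3 SDs of the empty spots, and the 138 probes detected in at least 3 of the 6 samples were tested; 105 of them were detected in all 6. Detection varied between arrays, from 110 probes in regenerating replicate 2 to 217 in regenerating replicate 1, so a filter against the mismatched control spots was added as an alternative after the data were examined. Median intensity of the empty spots ran from 43.0 to 560. The offset pulls changes of dim probes towards 0.

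Groups were compared with limma (lmFit and eBayes without trend) with a term for dye, and p-values were adjusted by the Benjamini-Hochberg method over the 138 probes with a threshold of 0.05. Changes are regenerating minus uninjured on the log2 scale, each with its standard error (SE). Lists of miRNAs were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 12 of 18 lists with at least 3 detected members; camera with an estimated correlation and fry were alternatives. The tests, lists, alternatives and the rule for named probes were fixed before the data were examined. That rule took every probe past the threshold whose groups did not overlap, up to 12 in each direction. Because fewer than 10 passed, it took the 10 smallest unadjusted p-values. It added up to 4 detected members of each list with the largest size of change, and a fixed set: miR-101a, miR-133a, miR-133b, miR-1, miR-499, miR-21, miR-223, miR-142a, miR-146a, miR-155, miR-451, miR-144, miR-126, miR-143, miR-145, miR-210, let-7a, miR-29b, miR-206 and miR-203a. Probe names that match a fixed name apart from the arm were included.

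Alternatives covered the background correction, its offset, the normalization (cyclic loess, 75th percentile, median), the authors' processed values, the detection filter, the median of spots, the dye, the replicate number as a block, a shared array as a block, an eBayes trend, the threshold and leaving out each sample. Scaling to the calibration spots, a correction for the G and C content (GC) of the target and the mismatch filter were added after the data were examined. Samples of opposite dye may share an array: the residual pattern of the 1060 empty spots correlated at a Spearman rho of 0.46 between uninjured replicate 2 (Cy5) and regenerating replicate 1 (Cy3), and at most 0.23 between any other pair. The shared-array block joined uninjured replicate 2 and regenerating replicate 1, a pair picked from this correlation and so from the data themselves. The number of samples limits the precision.

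The steps were tested on simulated spots in 20 runs, with 138 probes tested in the median run. Of the 10 probes per run changed by 1 log2 unit, 54.5% were recovered, and of the 10 changed by 2 log2 units, 85%; the median estimates were 0.83 and 1.76. Among the 317 calls 38 were false (12.0%), above the 0.05 that the threshold sets, and 1 of 20 runs without any change gave a call. With 75th percentile scaling the same simulation recovered 46% and 75.5%, with 5 false of 248 calls. In a simulated shift of 1 log2 unit of the miR-17-92 list, added to normalized values, camera called that list and 0 others. Noise was drawn separately for each probe and no GC trend was put in, so error rates in the real data may differ. In the real lists the estimated correlation between probes reached 0.62.

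Probe names are those of the array's design. Of the 218 probes, 163 matched a gene or synonym in the RefSeq table of the GRCz12tu assembly, which was used only for names and for which genes lie within 10000 bases of each other. Near-identical targets can share signal, so values of members of 1 family are not fully separate. Among the named probes, for example, the targets of miR-27b and miR-27d, miR-99 and miR-100, miR-200a and miR-141, let-7a and let-7g, and miR-133b and miR-133c lie at an edit distance of 1.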

Results

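Levels of 218 zebrafish miRNAs were measured in the hearts of adult fish without injury (3 samples) and 6 hours after partial amputation of the heart (3 samples), each sample a pool of hearts. Zebrafish regrow the lost part of the ventricle, and the comparison asks which miRNAs differ in the first hours. Over the 138 detected probes, samples correlated at r of 0.989 to 0.996 within the uninjured group, 0.977 to 0.990 within the regenerating group and 0.964 to 0.980 between the groups. The first principal component held 56.0% of the variance and separated the groups.

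In the regenerating samples miR-738 and miR-129 read higher with this processing, and miR-29b, miR-29a and miR-200b read lower. The calls of the 3 that read lower did not hold with 75th percentile or median scaling. Of these 3, only miR-29b was called after GC correction. With this processing the largest change was that of miR-738, a miRNA described in zebrafish, from a normalized log2 intensity of 7.23 ± 0.089 (SD, n = 3) to 10.04 ± 0.38 (SD, n = 3), a 7.01-fold rise. miR-129, known from the brain, rose 2.43-fold, from 6.78 ± 0.023 to 8.06 ± 0.22 (SD, n = 3 each). It was above background in 2 of the 3 uninjured samples and in all 3 regenerating ones. Detection in regenerating replicate 1 says little, as 217 of the 218 probes counted as detected there. The size of the miR-129 rise depended on the processing, with log2 changes of 0.84 to 3.01 over the alternatives. miR-29b was 2.54-fold lower after amputation, at 8.82 ± 0.22 against 10.16 ± 0.17 (SD, n = 3 each), and its relative miR-29a was 1.58-fold lower, at 11.79 ± 0.054 against 12.44 ± 0.068. The miR-29 family represses collagens and other extracellular matrix genes. miR-200b, of a family that maintains epithelial cells, was 1.75-fold lower, at 7.47 ± 0.19 against 8.28 ± 0.026.

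These 5 were the probes past the threshold in limma, and in each of them all 3 regenerating samples lay beyond all 3 uninjured samples. The log2 changes were 2.81 (SE 0.22, adjusted p = 0.0029) for miR-738, 1.28 (SE 0.14, adjusted p = 0.0087) for miR-129, -1.35 (SE 0.17, adjusted p = 0.0127) for miR-29b, -0.81 (SE 0.13, adjusted p = 0.0352) for miR-200b and -0.66 (SE 0.12, adjusted p = 0.0494) for miR-29a, all in limma. A miR-29a gene and a miR-29b gene neighbour each other in the GRCz12tu annotation, and the target sequences of the 2 probes differ at an edit distance of 3, so part of their signal may be shared. Over all detected probes, 28 had an unadjusted p below 0.05 where 6.9 are expected if nothing differs; 12 of them were higher and 16 lower. The groups did not overlap for 33 probes (13 higher, 20 lower), or 23.9%, where chance gives 10%.

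The next 5 probes by p did not pass, though miR-101a and miR-206 did with a shared array as a block. miR-101a, which in mammals represses the histone methyltransferase EZH2, was 1.99-fold lower in the regenerating samples, at 10.29 ± 0.33 against 11.29 ± 0.058 (SD, n = 3 each; limma adjusted p = 0.0658). miR-206, a miRNA of skeletal muscle, had a log2 change of 2.47 (SE 0.63, limma adjusted p = 0.115), with single regenerating samples at 11.03, 9.02 and 8.37 and single uninjured samples at 7.10, 7.16 and 6.75. Log2 changes were -0.60 for miR-19b and -0.69 for miR-19c, members of the miR-17-92 family of clusters tied to proliferation, and -0.68 for miR-200c (limma adjusted p = 0.106, 0.115 and 0.115). The targets of miR-200b and miR-200c lie at an edit distance of 1 and those of miR-19b and miR-19c at 2, so these pairs cannot be fully separated.

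**Figure D1:**
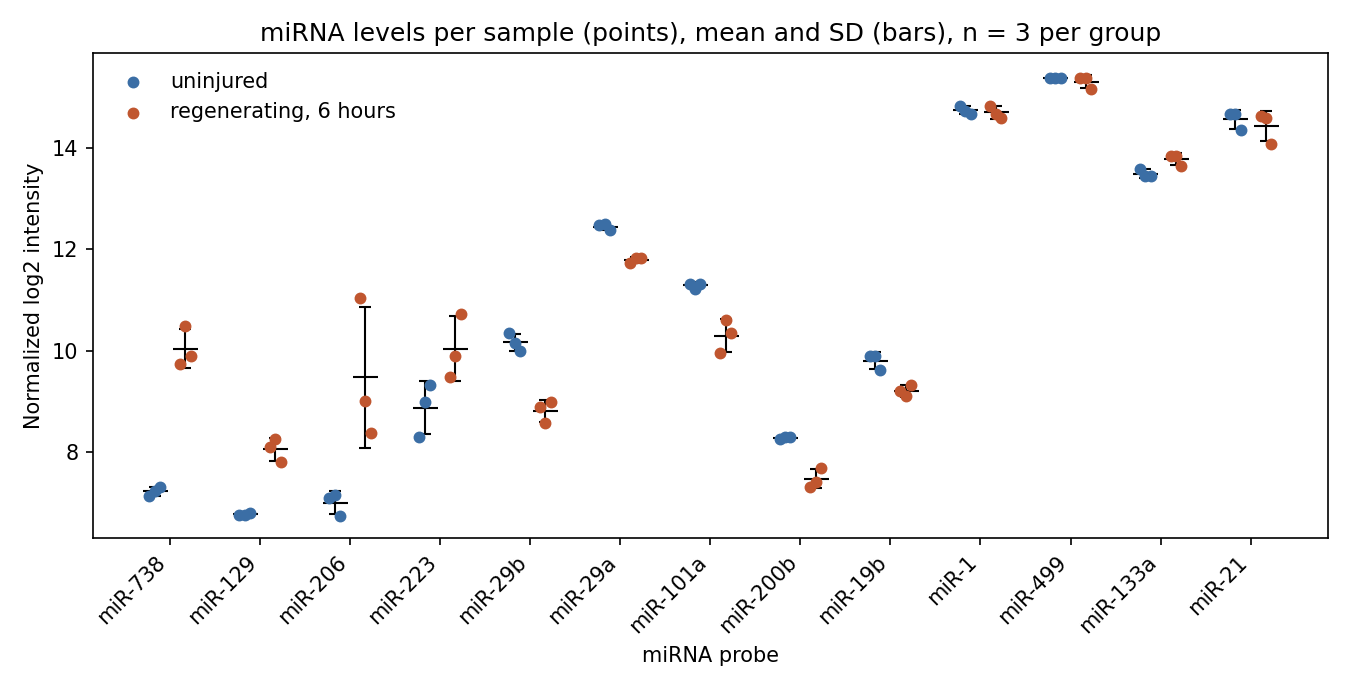
Normalized log2 intensity (vertical axis) of 13 miRNA probes (horizontal axis) in each of the 3 uninjured (blue) and 3 regenerating (orange) samples; bars give the mean and SD of a group. miR-738 sits between 9.74 and 10.47 in the regenerating samples and between 7.14 and 7.32 in the uninjured ones, while miR-206 is spread from 8.37 to 11.03 in the regenerating samples.

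The count of calls and its direction depended on scaling and on single samples. Scaling each array by 75th percentile, by the median or by calibration spots moved the median log2 change of all probes to 0.13, 0.46 and -0.80, against -0.052 with quantile normalization, and gave 5 rises and 0 falls, 31 rises and 0 falls, and 2 rises and 12 falls. Less that median, miR-738 stood at 3.08, miR-129 at 2.01, miR-29b at -1.23, miR-29a at -1.15 and miR-200b at -0.24 under each of these 3 scalings, and miR-206, which passed in all 3, at 3.16. Each of the 3 shifts an array by 1 factor, so these differences are equal by construction and their agreement is no separate evidence. The amounts of the calibration sequences are not given in the sources used here, so scaling to them takes the amounts as equal. The count was 1, 0 and 4 without uninjured replicate 1, 2 and 3, and 29, 2 and 0 without regenerating replicate 1, 2 and 3. Each 0 came from leaving out a Cy5 sample, which with the dye term leaves the comparison to the Cy3 samples. Over the alternative fits with a test, miR-738 passed in 22 of 25, miR-129 in 18 of 24, miR-29b in 16 of 25, miR-200b in 11 of 25 and miR-29a in 10 of 25, and none of the 3 falls passed with an eBayes trend. Of those not past the threshold here, miR-206 passed in 7 of 24, miR-101a in 6 of 25, and miR-146a and miR-223 in 3 of 25 each.

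The log2 change went with the GC content of the target across the 138 probes (Pearson r = 0.48, Spearman rho = 0.48, permutation p = 0.0001 for each, the smallest that 10000 permutations give; probes are not independent replicates). Without the 2 probes farthest from the median GC content r was 0.39. The median log2 change was -0.20 over the 54 probes with 27.3% to 40.9% GC and 0.11 over the 46 probes with 50% to 78.3% GC. miR-738 has 78.3% GC, the highest of the detected probes, miR-129 has 54.5%, and miR-29a, miR-29b and miR-200b have 36.4%. After a correction for this trend, chosen after the data were examined, 3 probes passed in limma: miR-738 at 1.89, miR-129 at 1.02 and miR-29b at -1.10. miR-29a stood at -0.41 and miR-200b at -0.56 with that correction (limma adjusted p = 0.199 and 0.163).

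**Figure D2:**
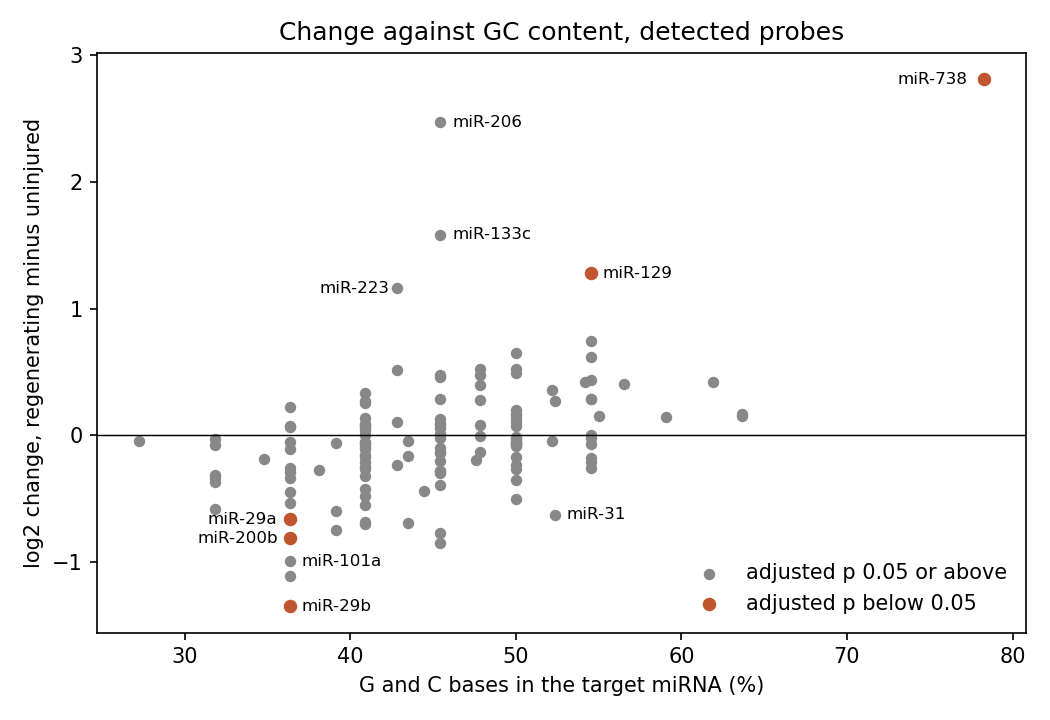
Log2 change between regenerating and uninjured samples (vertical axis) against the percent of G and C bases in the target miRNA (horizontal axis) for 138 detected probes; orange points passed the test. Higher GC content goes with a higher change (r = 0.48), and miR-738 stands alone at 78.3%.

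Among the miRNAs of heart and skeletal muscle, 0 of 7 detected probes passed. With this processing the best-known cardiac miRNAs showed small differences: miR-1, which represses proliferation of heart muscle cells, had a log2 change of -0.047 (SE 0.13), and miR-499, encoded within a myosin heavy chain gene, of -0.074 (SE 0.12). With GC correction they stood at 0.45 and 0.30. With scaling to calibration spots, where the median of all probes was -0.80, they stood at -0.90 and -1.06. Neither passed in these fits. miR-133a, a repressor of heart muscle cell proliferation, stood at 0.28 (SE 0.12, limma adjusted p = 0.294) and miR-133b at 0.20 (SE 0.16). Their targets lie at an edit distance of 1. The other arm, miR-133a*, stood at -0.26, and miR-133b* was too dim to be tested. miR-133c, with a target at an edit distance of 2 from that of miR-133a, stood at 1.58 (SE 0.59, limma adjusted p = 0.220). The list had a median of 0.20 and was not called (camera adjusted p = 0.339). In the GRCz12tu annotation 1 miR-206 gene neighbours that of miR-133b and another that of miR-133c.

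Of the leukocyte and inflammation miRNAs, 0 of 7 detected probes passed, and they went both ways (list median 0.073, camera adjusted p = 0.811). miR-223, a miRNA of neutrophils and macrophages, was at 10.04 ± 0.64 against 8.87 ± 0.53 (SD, n = 3 each), a log2 change of 1.16 (SE 0.34, limma adjusted p = 0.131) in which all 3 regenerating samples lay above all 3 uninjured ones. miR-146a, induced by NF-κB, stood at -0.74 (SE 0.27, limma adjusted p = 0.220). It was at -0.34 without uninjured replicate 2. It passed with a shared array as a block, with scaling to calibration spots and without regenerating replicate 1. Further members were miR-181a at 0.40, miR-146b at 0.29, miR-21, induced in many injured tissues, at -0.13 (SE 0.19), and miR-155 at 0.073. With 1 sample left out, miR-146b ran from 0.051 to 0.70 and miR-181a from 0.26 to 0.60. Without regenerating replicate 1 miR-181a passed. Both arms of miR-142a were too dim to be tested.

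In the list of smooth muscle, fibroblast and epicardial miRNAs, 2 of 7 detected probes fell (miR-29a and miR-29b), 0 rose and 5 did not pass; the same 2 fell when adjusted over the list alone. The remaining members went both ways: miR-145, of vascular smooth muscle, stood at 0.44 (SE 0.15), miR-214 at 0.42 (SE 0.15) and miR-143 at -0.19 (SE 0.15). Of all 7 members, 3 lay above 0 and 4 below. The list as a whole had a median of -0.091 and was not called (camera adjusted p = 0.928). In the epithelial list, included as a marker of another tissue, 1 of 6 detected probes fell (miR-200b), 0 rose and 5 did not pass, and 2 fell when adjusted over the list alone (miR-200b and miR-200c). Here miR-200a stood at -0.42, miR-429 at -0.25, miR-141 at -0.28 and miR-203b at 0.46, the list median was -0.35, and its camera p of 0.0331 became 0.339 after adjustment. The direction turned with scaling. With 75th percentile and median scaling miR-200a stood at 0.47 and 0.79, and miR-200c at 0.067 and 0.39. The median of all probes was 0.13 and 0.46 in these fits. miR-203a, whose target lies at an edit distance of 1 from that of miR-203b, was too dim to be tested.

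The miRNA families of the cell cycle and of differentiation showed no called member. In the miR-17-92 clusters 0 of 14 detected probes passed and 10 were below 0 (median -0.16, camera adjusted p = 0.506); miR-18c stood at 0.22 and miR-17a* at -0.21. In the miR-23/27/24 clusters 0 of 8 passed, 5 were below 0, 2 above and 1 at 0 (median -0.27, camera adjusted p = 0.506), with miR-27b at -0.39, miR-27a at -0.35, miR-27d at -0.47 and miR-27e at -0.30. The let-7 family, regulators of differentiation, had 0 of 10 past the threshold, with let-7a at 0.078 (SE 0.12), let-7e at -0.37, let-7g at -0.34, let-7h at -0.33 and let-7j at -0.29 (median -0.052, camera adjusted p = 0.937). Leaving out a single sample brought the last 4 to -0.12, 0.10, -0.069 and 0.071 at the highest, so 2 of them changed sign. The miR-15/16 family had 0 of 8 (median -0.028, camera adjusted p = 0.928), with miR-16c at -0.44, miR-457a at 0.34, miR-15a at -0.28 and miR-15c at 0.27. With 1 sample left out, miR-16c ran from -0.87 to -0.14 and passed without regenerating replicate 1. In the same fits miR-15a ran from -0.38 to 0.016, miR-457a from 0.13 to 0.55 and miR-15c from 0.18 to 0.42.

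The miR-30 family had 0 of 6 past the threshold (median -0.037, camera adjusted p = 0.998), with miR-30e at -0.26, miR-30a at 0.13, miR-30c at 0.056 and miR-30b at -0.055. The miR-125 and miR-99/100 list had 0 of 5 (median -0.023, camera adjusted p = 0.937), with miR-100 at 0.12, miR-125a at -0.069, miR-99 at -0.068 and miR-125c at -0.023. Among the miRNAs tied to zebrafish heart regeneration in published work, 0 of 9 passed over all probes, and 1 fell when adjusted over the list alone (miR-101a); that list may draw on these same hearts, so this count is not independent evidence. Its median was 0.078 and its mean -0.12 (camera adjusted p = 0.928), and miR-101b, whose target lies at an edit distance of 1 from that of miR-101a, stood at -0.58. The camera direction was up for the miR-15/16, miR-30 and miR-125 lists although their medians and means were below 0.

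The liver, gut and pancreas list had 0 of 3 past the threshold (median 0.48, camera adjusted p = 0.811); miR-192 stood at 0.52, miR-122, the main miRNA of hepatocytes, at 0.48 (SE 0.46) and miR-216a at -0.20. miR-122, which sets that median, was detected in 1 of 3 regenerating samples and stood at -0.063 without regenerating replicate 1. With the authors' processed values miR-192 passed at 1.15 and the epithelial miR-203b at 0.89 (limma adjusted p = 0.0218 and 0.0429), and with 75th percentile scaling miR-122 passed at 1.59 (limma adjusted p = 0.0267). The remaining 6 lists had fewer than 3 detected members, none of which passed. The erythroid list had 1 of 2 detected, miR-451 at 0.067 (SE 0.14), with miR-144 too dim to be tested. Both endothelial probes were detected, miR-126 at 0.10 (SE 0.13) and miR-126* at -0.27. Of the 4 hypoxia and stress probes 2 were detected, miR-210, induced by hypoxia, at 0.15 (SE 0.22) and miR-210* at 0.17. The list name miR-34a missed the tested probe miR-34, which matches the gene mir34a. With GC correction miR-34 stood at -0.37 (limma adjusted p = 0.394). The Hox cluster list had 1 of 8 detected, miR-10b at -0.047, the neural list 1 of 8, miR-128 at 0.088, and the miR-430 family of the early embryo 0 of 5.

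With camera, 0 of the 12 tested lists passed, and 1 had an unadjusted p below 0.05. With an estimated correlation 0 passed and the smallest adjusted p was 0.927; with fry, which asks whether a list moves one way on balance, 0 passed, 3 had an unadjusted p below 0.05 and the smallest adjusted p was 0.141. With 75th percentile scaling 2 lists passed in camera: liver, gut and pancreas (median 1.59, adjusted p = 0.0393) and the miR-23/27/24 clusters (median -0.45, adjusted p = 0.0393), where the median of all probes was 0.13.

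**Figure D3:**
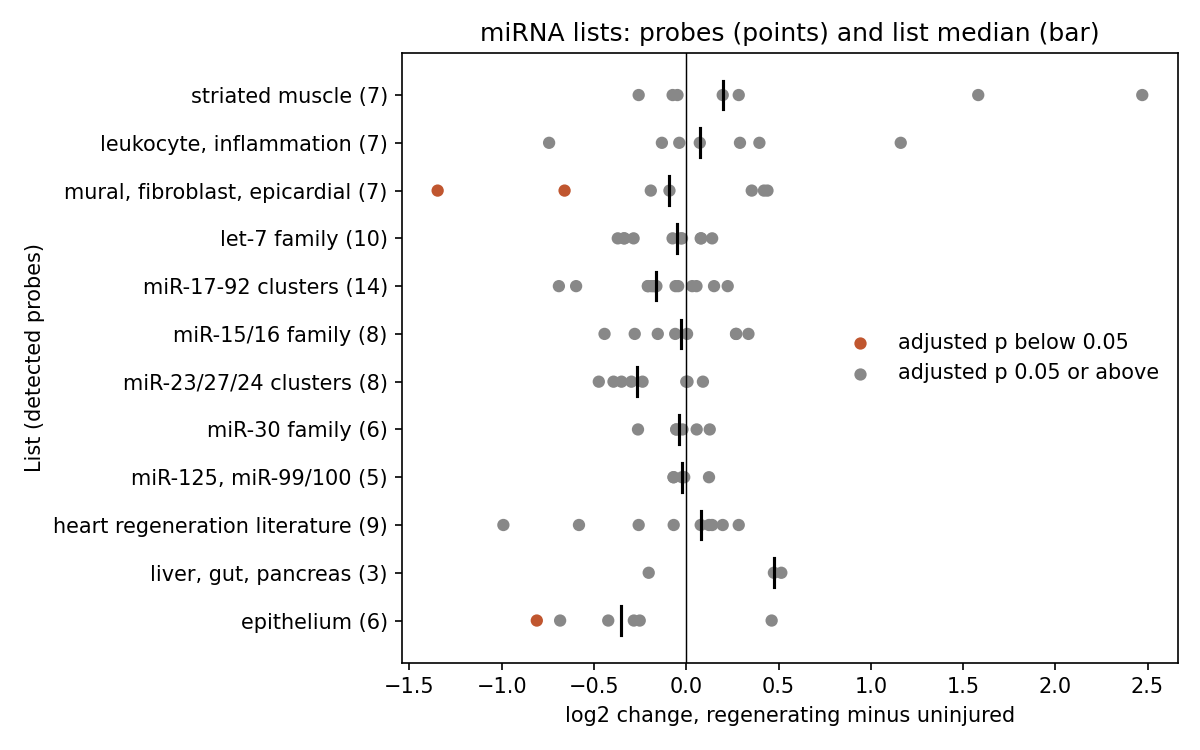
Log2 change between regenerating and uninjured samples (horizontal axis) of the detected probes of the 12 tested lists (vertical axis, number of detected probes in brackets); bars give list medians and orange points passed the test. The 3 probes that passed in these lists, miR-29b, miR-29a and miR-200b, lie below 0, and list medians run from -0.35 to 0.48.

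The ratio of mean miRNA intensity to the geometric mean of 5 added calibration probes was 0.939, 1.02 and 1.06 in uninjured replicates 1, 2 and 3, and 1.01, 0.473 and 0.301 in regenerating replicates 1, 2 and 3; it measures the amount of miRNA only if equal amounts of calibration sequence were added. Regenerating replicate 1 also stood apart on the second principal component, at 4.37 where the other samples lay between -2.05 and 0.31.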

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

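Spots outside the comparisons, for 5S ribosomal RNA and for added calibration sequences, were examined on the background-subtracted scale without normalization. Of these 49 control probes 20 were above background on every array, and in 3 of the 20 all regenerating samples lay above all uninjured ones, where chance puts 5% of probes in that order; in 0 of the 20 were they all below. The 5S ribosomal RNA probe 5S-b4 read 3250 ± 774 in the regenerating samples and 855 ± 271 in the uninjured ones (SD, n = 3 each), a ratio of 3.80; the other 3 such probes above background on every array had ratios of 1.12, 1.10 and 1.69 with overlapping groups. The calibration probe Ctr10-3P read 770 ± 335 against 425 ± 67.2, a ratio of 1.81. The calibration probe Ctr07-3P read 34487 ± 4698 against 27165 ± 2642, a ratio of 1.27.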

How the results depend on the processing

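GC correction, scaling to calibration spots and the mismatch filter were chosen after the data were examined. The 5 probes called became 3 with plain background subtraction, 31 with median scaling, 3 with an eBayes trend (miR-738, miR-129 and miR-206, with 0 falls), 3 with GC correction, 14 with scaling to calibration spots, 11 at an unadjusted p below 0.01, and 0 with the Cy3 samples only, which leaves 4 samples. A shared array as a block gave 9; with 1 shared pair it was fitted as a fixed term. Leaving out 1 sample gave 0 to 29 probes (0 without uninjured replicate 2 or regenerating replicate 3, 29 without regenerating replicate 1). Those that gave 0 are the Cy5 samples. Without either of them the dye term absorbs the other, so these fits compare the groups on the Cy3 samples and repeat the fit above. The count of lists, 0, became 2 with 75th percentile scaling and stayed at 0 when each sample was left out. The other counts of probes were 4 to 6. The replicate block gave 1 probe with the dye term and 9 without it; same-numbered samples deviated together at r of 0.14, -0.45 and 0.37, so the numbers were not taken as pairs.

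Median scaling, with a median log2 change of 0.46 over all probes but unequal moves of single probes, turned miR-200b to 0.22, and turned miR-126*, miR-17a*, miR-10b and miR-216a from below 0 to calls at 1.22, 1.30, 1.51 and 1.36; the cause was not tested. Limma adjusted p-values over the alternatives ran from 5.14e-06 to 0.166 for miR-738, 1.82e-04 to 0.129 for miR-129, 0.0037 to 0.184 for miR-29b, 0.0147 to 0.862 for miR-200b and 0.0147 to 0.336 for miR-29a. Among 1570 values of 61 named probes, 38 gained and 46 lost a call, and 106 changed sign without a call; 18 values from the Cy5 samples alone, 1 per group and without a test, moved by over 1 SD. Array signal over background limits probes such as miR-129, miR-206 and miR-192, which were near background in the uninjured samples.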

Other observations

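The tests of miR-206, of miR-29b alone, of scaling for miR-29a with miR-29b and for miR-200b, and of probe brightness were chosen after the result was seen, as were the probes named in the next sentences; the GC correction and the scaling to calibration spots were likewise added later. Among probes that no list held, miR-462 and miR-731, which are induced together by interferon in fish, had log2 changes of -0.85 and -0.50 (limma adjusted p = 0.244 for both). miR-221 and miR-222, which share a cluster, stood at 0.28 and 0.42 (limma adjusted p = 0.324 and 0.131), and for both all 3 regenerating samples lay above all 3 uninjured ones. miR-25 stood at 0.50 (limma adjusted p = 0.130), while miR-93, from the same cluster in the GRCz12tu annotation, stood at 0.032. miR-724 stood at -1.11, miR-152 at -0.77 and miR-31 at -0.63 (limma adjusted p = 0.130, 0.115 and 0.130), each lower in 3 of 3 regenerating samples than in any uninjured one. In the alternatives miR-724 passed with a shared array as a block and with scaling to calibration spots, and miR-152 with the replicate block without the dye term. Without regenerating replicate 1, where 29 probes passed, miR-724, miR-152, miR-462, miR-25 and miR-222 were among them.

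The rise of miR-738 and miR-129 might come from the trend with GC content or from unspecific binding. With GC correction the smaller of their log2 changes, that of miR-129, was 1.02, with a lower 95% bound of 0.67, and both passed in limma. For miR-129 this argues against the trend as the whole cause. For miR-738 it cannot decide, because that probe stands alone at 78.3% GC and no probe of like GC shows whether the straight line holds there. The median of 22 mismatched control probes gained 11.6% of the intensity that miR-129 gained. A gain of that size, shared by all probes, would fall short of the rise of miR-129. Mean unspecific binding was not level between the groups, though. Mean intensity of the 22 probes rose by ratios of 1.71 to 13.7, most of them dim in the uninjured samples. Of the 22, only Ctr07-3M05 had all 3 regenerating samples above all 3 uninjured ones. The 2 mismatched probes Ctr09-3M05 and Ctr09-3M10, of 1 calibration sequence, gained more than miR-129. In both, regenerating replicate 1 read within the uninjured range, so the groups overlapped, unlike those of miR-129 and miR-738. These 2 probes therefore do not show a rise in all 3 regenerating samples, but unspecific binding that differs between probes stays open. A biological rise in regenerating hearts remains a hypothesis, and the share that GC content adds to miR-738, whose change went from 2.81 to 1.89, stays open.

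The fall of miR-29a, miR-29b and miR-200b could reflect their low GC content, scaling, or bright probes reading low on the dimmer regenerating arrays. Relative to all probes, where 1 factor per array cancels, miR-29a stood at -1.15 (SE 0.33) and miR-29b at -1.23 (SE 0.34). This argues against 1 factor per array as the source of their place below the other probes, but not against a shift that depends on brightness. Both passed with cyclic loess and with scaling to calibration spots. Neither passed with 75th percentile scaling (limma adjusted p = 0.0659 and 0.0742) or median scaling (limma adjusted p = 0.143 and 0.127), so their calls depended on scaling. For miR-200b, at -0.24 (SE 0.38), scaling stays open. For miR-29b GC correction left -1.10 with a limma adjusted p of 0.0398, and its log2 change less the median of the 20 probes nearest in brightness was -1.20 (SE 0.35), so neither is the whole cause for that probe, and a lower level in regenerating hearts remains a hypothesis. For the 3 together GC correction took the median from -0.81 to -0.56; the calls of miR-29a (-0.66, SE 0.12, to -0.41, SE 0.15) and miR-200b (-0.81, SE 0.13, to -0.56, SE 0.14) ended because the changes shrank while the SE did not, so GC content stays open for them. Brightness stays open for miR-29a at -0.61 (SE 0.28), although it too lay below each of its 20 neighbours, and the value of -0.66 (SE 0.47) for miR-200b decides nothing, as its neighbours had a median of 0.55 and did not read low.

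The higher miR-206 values might come from miR-1 binding to the miR-206 probe, whose target lies at an edit distance of 4, or from another tissue taken with the heart. The upper 95% bound of the miR-1 log2 change was 0.28, far below the change of 2.47, which argues against a rise of miR-1 as the source. More binding of an unchanged miR-1 was not excluded by this. The mismatched calibration probe Ctr09-3M10 had a ratio of 13.7 between the groups, while its matched partner Ctr09-3P had 1.23. That ratio rests on regenerating replicates 2 and 3, at 2677 and 8433. Regenerating replicate 1 read 92.5, within the uninjured values of 61.5 to 655, so the groups overlapped, unlike those of miR-206. Of 10 detected markers of neural, liver, gut, pancreas and epithelial tissue, 2 (miR-203b and miR-192) lay above all uninjured samples in all 3 regenerating samples. Another tissue therefore cannot be told apart from a change within the heart. With the authors' processed values both markers passed in limma, at 0.89 and 1.15. Skeletal muscle was not among the tissues tested. The tested probes miR-129, known from the brain and called higher here, and miR-217 matched no name in these lists and were not counted. Another tissue as the source of the miR-129 rise was not tested.

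With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5 probes and the highest of the other splits 0; 1 of the 10 gave as many as the real one, the real one itself. At an unadjusted p below 0.05 the real split gave 28 probes and the highest other 16. For lists the real split gave 0 and the highest other 1, and 10 of 10 gave as many.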
